A study of Mus musculus with 4 samples.

How the data were processed

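Droplet-based single-cell RNA sequencing (10x Genomics) was done on MC38b tumours grown in mice and treated with saline (PBS), with an antibody against PD-1, or with antibodies against PD-1 and TL1A. The design text states that tumours were taken 24 h after the second dose, digested and stained for CD45 and CD3. Cells of 3 gates (CD45 and CD3 positive, CD45 positive and CD3 negative, both negative) were sorted and remixed at 9 to 9 to 2 parts, and 20000 cells were loaded per condition. Libraries were sequenced on a NovaSeq instrument. Because the remix sets the proportion of the gates, shares of cell types were compared only within a gate. There were 4 libraries in 3 groups: 2 of PBS, 1 of anti-PD-1 and 1 of anti-PD-1 plus anti-TL1A. The text gives 2 saline and 4 treated animals and says that animals were pooled before sorting, without saying whether each PBS library is 1 animal or a pool. The p-values for single genes therefore measure only the spread between these libraries, which may be technical. A chi-square test of the summed PBS counts gave 1.364e+06 on 19572 degrees of freedom, or 69.7 per degree. The pair was therefore not treated as repeat deposits. This does not show separate animals, since cells of 1 pool also differ by more than sampling noise. The pair shares 673 barcodes, not tested against chance.

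The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and barcode, per the file headers, for barcodes that had already been filtered. The submitters' processing notes name Cell Ranger 3.0.2 and mm10, whereas the matrices were written by Cell Ranger 7.1.0, per the file headers. Whether intronic reads were counted is not given in the sources used here. Positions are those of GENCODE M21 on GRCm38, the build that mm10 names. For each gene named, the 31-base stretches in the last 500 bases of its longest transcript were searched in all other genes, and genes that share over 10% of them are given once as uncertain, with that share.

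Before the data were examined, the groups, the tests, 29 gene lists, markers of 22 cell types, the rule for naming genes and most alternatives were fixed. Barcodes with at least 200 genes and under 15% mitochondrial UMIs were kept. Scrublet scores were computed per library with scanpy 1.11.5; its automatic threshold marked at most 0.0761% of cells, so the cells with the highest scores were removed at the expected rate of 0.8% per 1000 barcodes (354, 324, 1364 and 975 cells in PBS 1, PBS 2, anti-PD-1 and anti-PD-1 plus anti-TL1A). That left 6219, 5957, 11523 and 9932 cells. Cells were clustered with Leiden (2000 variable genes, 30 and then 20 principal components, 20 neighbours, resolution 1 and then 1.5 in the T and other immune gates and 0.8 in the CD45-negative gate; igraph 0.11.9, seed 1). Gates were assigned from mean Ptprc and Cd3e (200 CPM each), and clusters were named from the fixed markers with thresholds set after seeing the data (100 CPM for Foxp3, Cd8a and Cd4, 500 CPM for Mki67). T cell clusters past both the Cd8a and the Cd4 threshold were named CD8. Clusters with a median under 2000 UMIs or with markers of 2 lineages were left out of the classes and of their denominators. Unnamed clusters stayed in the denominators, among them a CD45-negative cluster with a median of 3550 UMIs (10000 were asked there), led by Acta1, Tpm2 and Des, with 6.38%, 22.4%, 24.1% and 6.96% of its gate. The planned tumour class could not be told apart from stroma by the fixed markers and was analysed as CD45-negative cells. Foxp3 and Cd8a separate the T cell classes, so these genes and the other markers used for naming are not results of the comparisons between classes.

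Raw counts were summed per class and library and tested with edgeR 4.0.16 in R 4.3.3: TMM normalisation, a filter on low counts (filterByExpr, minimum 10), a robust quasi-likelihood fit of all 4 libraries by group, and Benjamini-Hochberg adjustment within a class and comparison, with 0.05 as the threshold. Only the PBS pair gives a residual degree of freedom (1), shared across genes, and each treated library is assumed to vary as the PBS libraries do. The comparison of the 2 treated libraries compares those libraries, not the conditions. CPM values are TMM-normalised, and errors are standard errors (SE) derived from the F statistic. The biological coefficient of variation was 8.87% in CD8 T cells, 11.2% in conventional CD4 T cells, 9.74% in regulatory T cells, 7.82% in monocytes and macrophages, 23.9% in neutrophils, 9.08% in CD45-negative cells and 9.72% in NK cells. The weight that the fit gave to the spread over all genes differed between classes, so counts of genes are not compared across classes. Gene lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation of 0.01 and, as an alternative, an estimated one. Adjustment was over the 104 list tests of a comparison. Shares are given with exact Clopper-Pearson 95% intervals and have no test; intervals and limits for counts of 0 (3 counts) cover counting error only. For shares of cells with a UMI, cells were also thinned to 1000 UMIs.

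The test was run on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold per class and comparison. For anti-PD-1 minus PBS, at 2-fold, recovery was 99% in CD8, 70% in conventional CD4 and 83% in regulatory T cells. It was 100% in monocytes and macrophages, 9% in neutrophils and 100% in CD45-negative cells. Between the treated libraries neutrophils had 0% at 2-fold and 1% at 4-fold. Each fit had 0 to 12 false calls, and 18 of 18 changed and 0 of 360 unchanged lists were called. Shifts under 2-fold and correlated genes were not simulated.

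Named genes are, per class and comparison, the 3 largest rises and the 3 largest falls among genes past the threshold with at least 50 CPM in the higher group. Up to 4 members with the smallest p of each list past the threshold and the genes of the TL1A and PD-1 axis were added, and the text gives a part of these; some genes that the rule names are not reported here. Predicted, mitochondrial, ribosomal, immunoglobulin, receptor-segment and Y-linked genes were left out. Alternatives planned beforehand were DESeq2 1.42.0 (Wald test), RLE size factors, no filter beyond 1 count, a strict cell filter (500 genes, 10%), doublets kept, a higher resolution, an estimated correlation, thinning of cells, and leaving out each PBS library. Added after seeing the data were low-UMI clusters kept, clusters named before a rule on their top 10 genes, class sums thinned to equal totals, a fit without the anti-PD-1 library, monocyte or macrophage clusters alone, class shares with clusters of 2 lineages kept under their best-scoring class, and NK cells as a further class. Other software was Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.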

Results

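The libraries came from mouse tumours grown from MC38b cells (MC38 is a mouse colon carcinoma line) after 2 doses of saline, anti-PD-1 or anti-PD-1 plus anti-TL1A. PD-1 is an inhibitory receptor of activated T cells, and TL1A, encoded by Tnfsf15, is a cytokine of the TNF family whose receptor, DR3, is encoded by Tnfrsf25. By its title, the series asks what anti-TL1A adds to checkpoint treatment with anti-PD-1. The files held 6732 barcodes in PBS 1, 6448 in PBS 2, 13231 in the anti-PD-1 library and 11177 in the library of both antibodies, called the combination library here. Total UMIs were 92495603, 78648222, 82816801 and 142600208 in the same order, and median UMIs per barcode were 7798, 7645.5, 3588 and 7098. The anti-PD-1 library thus had the shallowest cells, and 26.7% of its kept cells lay in low-UMI clusters that were left out, against 5.66% and 14.1% in the PBS pair and 2.31% in the combination library. Each treated arm had 1 library, so every comparison below rests on the spread between the PBS pair.

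Among T cells, CD8 T cells made up 39.3% (95% interval 37.5 to 41.2) and 40.3% (38.4 to 42.3) in the PBS pair, 41.9% (40.4 to 43.5) in the anti-PD-1 library and 44.6% (43.2 to 46.1) in the combination library. Regulatory T cells, the Foxp3-expressing suppressive subset, made up 16.1% and 18.0% in PBS, 17.8% under anti-PD-1 and 12.9% (12.0 to 13.9) in the combination library. That lower share depended on 2 clusters set aside for markers of 2 lineages, with Il2ra and Ctla4, and in the larger Foxp3, among their leading genes. They held 76, 114, 152 and 329 and 60, 22, 63 and 135 cells and entered no test of genes. Counted as regulatory T cells they brought the shares to 19.97%, 22.2%, 21.9% and 20.6%, and the log2 ratio of the combination library over PBS from -0.40 to -0.034, while that of CD8 T cells went from 0.16 to 0.10. Conventional CD4 T cells stood at 14.7% and 15.7% in PBS against 12.1% and 12.2% in the treated libraries. Among CD3-negative immune cells, monocytes and macrophages made up 34.0% and 33.6% in PBS, 30.2% under anti-PD-1 and 27.4% in the combination library. Neutrophils made up 5.82% and 9.32% in PBS, 4.03% under anti-PD-1 and 5.03% in the combination library, and the PBS pair differed by more than PBS 1 and the combination library. Shares were given no test. With low-UMI clusters kept, the log2 ratio of anti-PD-1 over PBS for monocytes and macrophages went from -0.16 to 0.22, that for regulatory T cells from 0.06 to -0.094 and that for NK cells from 0.26 to 0.089. In the same setting CD8 T cells went from 0.07 to 0.38 and conventional CD4 T cells from -0.33 to -0.67, and at the higher resolution regulatory T cells of the combination library went from -0.40 to -0.24. Without 1 PBS library, the ratio for neutrophils under anti-PD-1 ranged from -1.21 to -0.53.

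**Figure D1:**
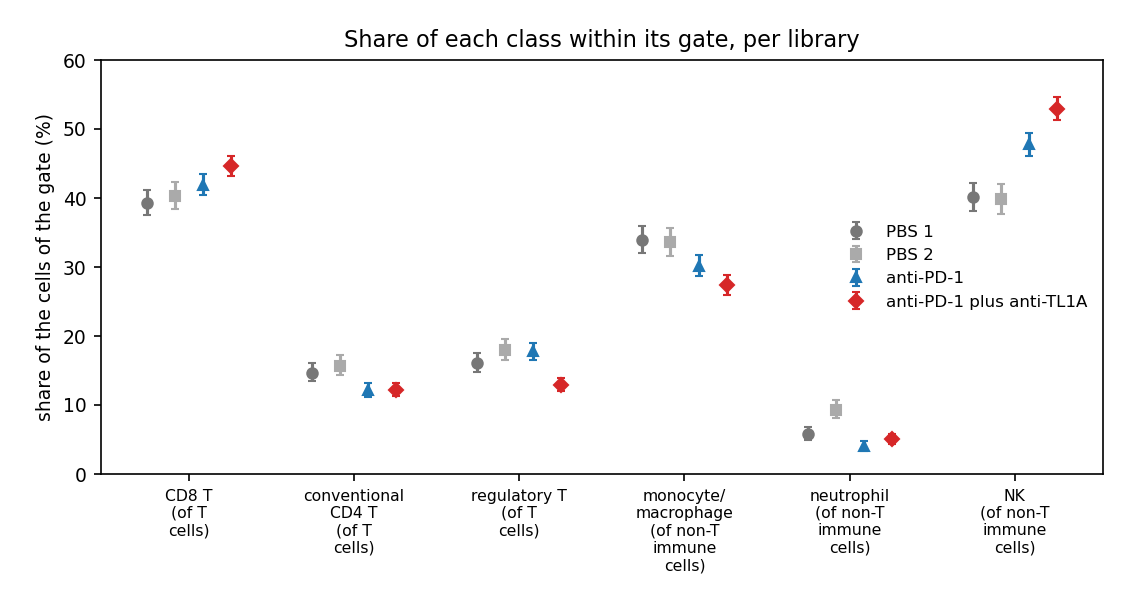
Share of cells (%) of each class within a gate assigned per cluster from Ptprc and Cd3e transcripts, without low-UMI and mixed clusters, 1 point per library, with exact 95% intervals that cover counting error only. Regulatory T cells of the combination library (12.9%) lie below the other 3 libraries, but at 20.6% against 19.97% to 22.2% with 2 mixed clusters counted among them, and NK cells of both treated libraries (47.8% and 52.9%) lie above the PBS pair (40.1% and 39.8%), a log2 ratio under anti-PD-1 of 0.26, or 0.089 with low-UMI clusters kept.

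Transcripts of the targets themselves were compared next. Tnfsf15 (ENSMUSG00000050395, chromosome 4, 63727084 to 63745113, minus strand, GRCm38) was scarcely detected. Monocytes and macrophages held 8, 14, 5 and 14 UMIs in PBS 1, PBS 2, anti-PD-1 and combination, or 0.669, 1.17, 0.599 and 1.20 CPM. Dendritic cells held 5, 2, 2 and 1 UMIs. A difference in the TL1A transcript was not detectable at this depth. Tnfrsf25 (ENSMUSG00000024793, chromosome 4, 152115934 to 152120119, plus strand) was highest among the classes compared in conventional CD4 T cells, at 13.6, 14.0, 16.8 and 7.73 CPM. Gamma-delta T cells, which were not compared, had 11, 0, 5 and 16 UMIs in 45, 10, 51 and 57 cells, or 42.0, 0, 25.6 and 51.8 CPM without TMM, and the 0 of 10 cells allows a share of cells with a UMI of up to 30.0%. The combination library differed from PBS by -0.83 on the log2 scale, which did not pass edgeR's test (adjusted p = 0.76). Of conventional CD4 T cells, 6.44%, 7.93%, 5.56% and 3.93% had a Tnfrsf25 UMI, and 1.44%, 0.256%, 1.66% and 1.03% after thinning to 1000 UMIs, which left out 1, 0, 4 and 1 cells. Regulatory T cells had 3.19, 5.42, 2.24 and 2.68 CPM, and neither treated library passed there (adjusted p = 0.685 and 0.838, edgeR). Of regulatory T cells, 1.96%, 3.79%, 0.842% and 1.46% had a Tnfrsf25 UMI, on 9, 19, 6 and 9 UMIs, and 0.652%, 0.446%, 0.141% and 0.324% after thinning (3, 2, 1 and 2 cells), which left out 0, 0, 2 and 0 cells. Monocytes and macrophages, which should lack the receptor, held 0, 0, 2 and 0 cells with a UMI at median depths of 11615, 12902, 6234.5 and 8565 UMIs, against 4871, 5573, 3368 and 4502 in conventional CD4 T cells. The 0 of 794 cells in PBS 1 allows a share of cells with a UMI, not of cells expressing the gene, of up to 0.378%, the 0 of 685 in PBS 2 up to 0.438% and the 0 of 975 in the combination library up to 0.308%.

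Pdcd1, which encodes PD-1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553, minus strand), had a UMI in 43.4%, 54.3%, 48.5% and 58.9% of CD8 T cells, and in 12.5%, 13.1%, 14.0% and 14.8% after thinning, which left out 1, 0, 16 and 2 cells. Background in CD45-negative cells was 0.568%, 2.52%, 0.98% and 1.57% at median depths of 68233, 79266, 46920 and 64014 UMIs, against 8475, 9952, 5751 and 8242 in CD8 T cells. Its CPM in CD8 T cells did not pass the test in either treated library (log2 fold change 0.22, adjusted p = 0.48 under anti-PD-1; 0.02, adjusted p = 0.95 in the combination library, edgeR). Nor did it pass in conventional CD4 T cells (0.54 ± 0.21, adjusted p = 0.289, and 0.26 ± 0.20, adjusted p = 0.949) or regulatory T cells (0.46 ± 0.19, adjusted p = 0.378, and 0.20 ± 0.18, adjusted p = 0.827). Cd274, which encodes the PD-1 ligand PD-L1 and is induced by interferon-gamma (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095, plus strand), rose in monocytes and macrophages by 0.76 ± 0.11 (SE, adjusted p = 2.4e-08) under anti-PD-1 and by 0.95 ± 0.10 (adjusted p = 3.3e-12) in the combination library on the log2 scale. In CD45-negative cells it rose by 0.76 ± 0.13 (adjusted p = 6.8e-05) and 1.11 ± 0.12 (adjusted p = 2.0e-09), and the difference of 0.35 ± 0.14 between the treated libraries did not pass (adjusted p = 0.18). In neutrophils it was high in all libraries (870, 1855, 1880 and 1362 CPM) and differed more within the PBS pair than between PBS 2 and either treated library. In the monocyte clusters alone the rise under anti-PD-1 was 0.55 and no longer passed the test.

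**Figure D2:**
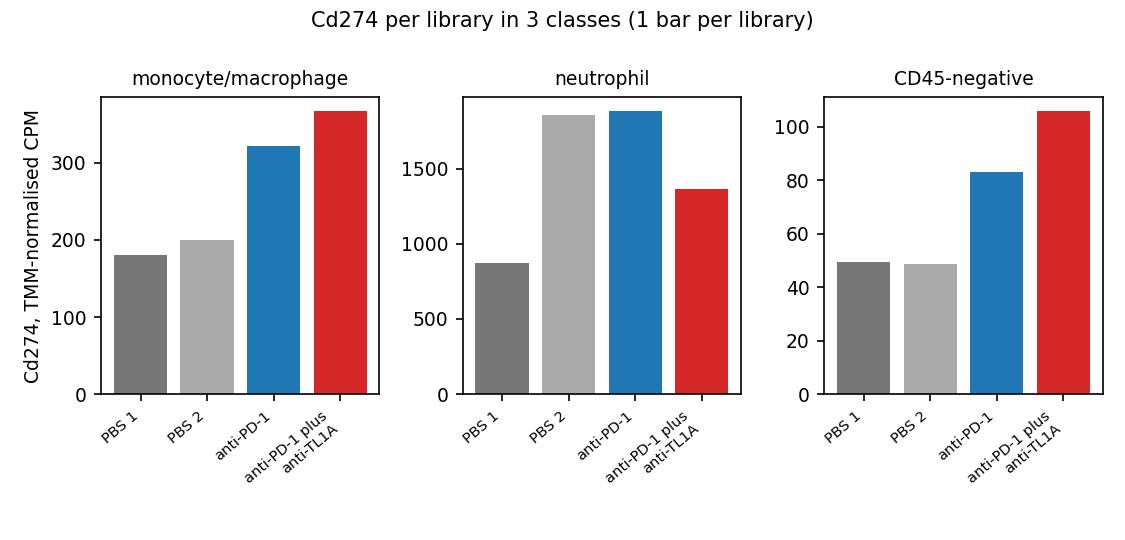
Cd274 in 3 classes as TMM-normalised CPM of the summed UMIs, 1 bar per library and 1 scale per panel, each starting at 0. In monocytes and macrophages both treated libraries (322 and 367 CPM) exceed the PBS pair (180 and 200 CPM), in CD45-negative cells 82.9 and 106 CPM exceed 49.4 and 48.7 CPM, and in neutrophils the PBS pair itself spans 870 to 1855 CPM.

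CD8 T cells of the anti-PD-1 library carried more transcripts of granzymes, the serine proteases of cytotoxic granules, than those of PBS. Gzmd rose from 5.70 and 4.36 CPM to 56.5 CPM (log2 fold change 3.49 ± 0.16, adjusted p = 1.9e-06). Gzme rose from 6.26 and 5.64 to 56.0 CPM (3.23 ± 0.15, adjusted p = 1.9e-06) and Gzma from 152 and 151 to 561 CPM (1.89 ± 0.11, adjusted p = 1.4e-05). Gzmg, at 0.09 CPM in each PBS library, reached 5.96 CPM. For each gene list, the first count given is of members past the threshold over all genes and the second is adjusted over the list alone. Of the 26 tested cytotoxic effector genes, 8 rose over all genes and 13 adjusted over the list alone (median 0.55; camera adjusted p = 3.2e-10, and adjusted p = 0.975 with an estimated correlation). Genes of naive or memory T cells fell as a list of 17 (median -0.41, adjusted p = 0.00064), with 0 past the threshold over all genes and 5 lower adjusted over the list alone, and adjusted p = 0.975 with an estimated correlation. Among single genes, Patj, a cell polarity protein, fell by 0.82 ± 0.13 and Jmy, an actin nucleator, by 0.61 ± 0.12. Btg2, of the handling stress list, fell by 0.67 ± 0.12. Beside these groups, the share of CD8 T cells in a cluster led by Lef1 and Tcf7 differed between libraries, with 319 of 1121, 223 of 1005, 281 of 1683 and 188 of 2135 cells.

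Gzmd and Gzme share bases (37.7% and 45.5% of their last stretches occur in other genes, mostly in each other), as do Gzmg (31.9%) and Gzmf (21.1%). All lie on chromosome 14 within 56117626 to 56211417, so the split of UMIs between them is uncertain. Gzmf is also among the leading genes of 2 CD8 clusters, and Gzmb of 1. Oxidative phosphorylation genes, which encode the respiratory chain, rose in CD8 T cells under anti-PD-1 (38 genes, median 0.36, adjusted p = 6.7e-09), with 3 past the threshold over all genes and 24 adjusted over the list alone. Also higher were cell cycle genes (41 genes, median 0.23, adjusted p = 0.0046), with 1 and 3 genes, of which Nusap1, a mitotic spindle protein, rose by 1.30 ± 0.24. So were hypoxia and glycolysis genes (25 genes, median 0.18, adjusted p = 0.02), with 0 over all genes and, adjusted over the list alone, 9 higher and 1 lower. A list of regulatory T cell function genes was higher (20 genes, median 0.27, adjusted p = 0.00063), with 1 and 4 genes. The member past the threshold was Tnfrsf4, the costimulatory receptor OX40, which activated CD8 T cells also express (0.63 ± 0.11). Handling stress genes were lower (20 genes, median -0.29, adjusted p = 0.0015), with 1 and 6 genes. Neutrophil markers were higher (5 genes, median 0.55, adjusted p = 0.02), with 1 and 1 gene, Il1r2, a decoy receptor for interleukin-1 (1.15 ± 0.18). All 6 of these lists had adjusted p = 0.975 with an estimated correlation. Over all 13986 genes tested in CD8 T cells, edgeR called 81, 68 higher and 13 lower, of which 20 changed at least 2-fold. That count ranged from 47 with DESeq2, of which 23 were among the 81, to 716 after class sums were thinned to equal totals. The higher resolution ended the call of Nusap1.

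In CD8 T cells of the combination library, granzymes, perforin and osteopontin were higher than in PBS while genes of naive and memory cells were lower. Gzmd rose by 3.44 ± 0.16 (adjusted p = 2.4e-06). Gzmb, the main granzyme of effector CD8 T cells, rose from 359 and 438 to 1084 CPM (1.44 ± 0.16, adjusted p = 0.0023), and Prf1, the pore-forming perforin, from 113 and 133 to 277 CPM (1.17 ± 0.12, adjusted p = 0.0016). Spp1, which encodes the secreted phosphoprotein osteopontin, rose from 19.8 and 15.5 to 97.4 CPM (2.47 ± 0.14, adjusted p = 9.3e-06). Cxcr5, a follicle homing receptor, fell by 1.52 ± 0.21, and Lef1 and Tcf7, transcription factors of naive and stem-like T cells, fell by 0.77 ± 0.13 and 0.85 ± 0.14. Patj fell by 1.27 ± 0.13 and Snhg12, a noncoding RNA, fell by 1.16 ± 0.16. The cytotoxic list had 11 members higher over all genes and 15 adjusted over the list alone (median 0.56, adjusted p = 4.6e-11). The naive or memory list had 6 lower and 11 adjusted over the list alone (median -0.59, adjusted p = 7.3e-09). Both had adjusted p = 0.795 with an estimated correlation. The Lef1 and Tcf7 cluster named above held the fewest of its cells in this library, 188 of 2135.

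Further lists were higher in CD8 T cells of the combination library. Regulatory T cell function genes (median 0.35, adjusted p = 0.00013) had 2 members past the threshold over all genes and 8 adjusted over the list alone, among them Ctla4, an inhibitory receptor of activated T cells (0.77 ± 0.13). Exhaustion genes (20 genes, median 0.23, adjusted p = 0.023) had 1 higher, and adjusted over the list alone 5 higher and 2 lower. Cell cycle genes (median 0.19, adjusted p = 0.0013) had 1 and 2, Cenpa, a centromere histone that shares 10.2% of its last stretches with other genes, being the 1 (0.69 ± 0.11). MHC class I pathway genes (17 genes, median 0.23, adjusted p = 0.0035) had 2 and 4, with the peptide transporter Tap2 at 0.60 ± 0.11. Type I interferon genes (28 genes, median 0.16, adjusted p = 0.0063) had 0 and 2. Interferon-gamma response genes (24 genes, median 0.12, adjusted p = 0.037) had 1, and adjusted over the list alone 1 higher and 1 lower. A cluster of this class led by interferon-induced Ifit3 and Ifit1 held 101, 122, 101 and 249 cells. It had Cd4 at 101 CPM beside Cd8a at 353 CPM and scored 1.31 for conventional CD4 against 1.49 for CD8 markers, so it was not clear of CD4 T cells. Hypoxia and glycolysis genes (median 0.14, adjusted p = 0.014) had 1 and 2, oxidative phosphorylation genes (median 0.11, adjusted p = 0.033) 0 and 0, and macrophage markers (12 genes, median 0.28, adjusted p = 0.0081) 0 and 0. With an estimated correlation, adjusted p was 0.847 for MHC class I, 0.862 for hypoxia, 0.934 for oxidative phosphorylation and 0.795 for the other 6 lists. By edgeR, 153 genes were called, 75 higher and 78 lower, 54 of them at least 2-fold. DESeq2 called 49, 30 higher and 19 lower, and thinning to equal totals gave 704.

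**Figure D3:**
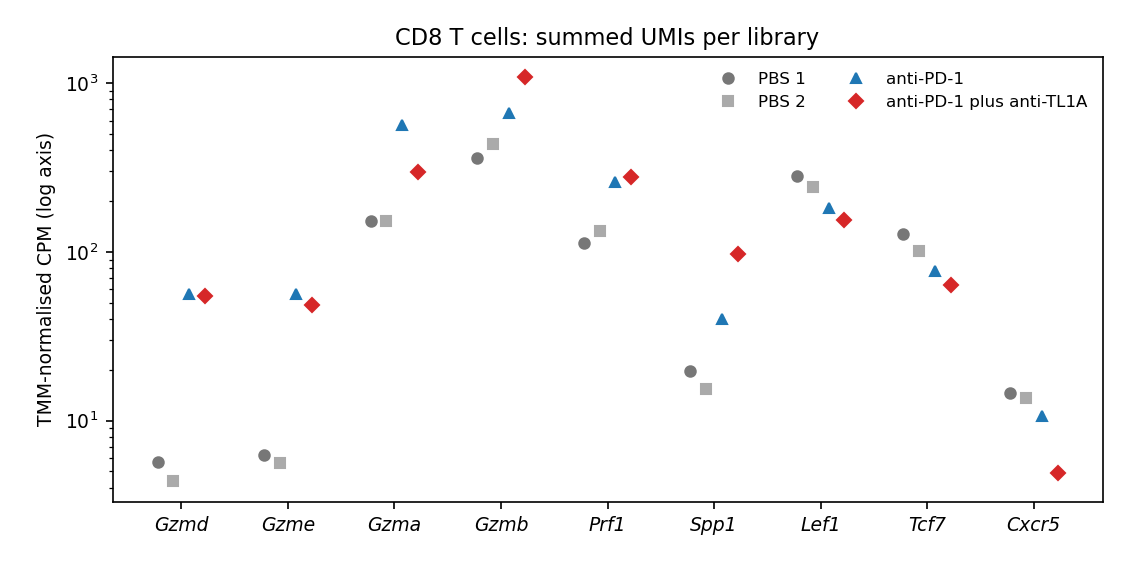
Named genes in CD8 T cells as TMM-normalised CPM of the summed UMIs on a log axis, 1 point per library. Granzymes, Prf1 and Spp1 lie higher in both treated libraries than in the PBS pair, and Lef1 (283 and 243 against 181 and 154 CPM), Tcf7 and Cxcr5 lie lower.

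Set against the anti-PD-1 library, CD8 T cells of the combination library had more Spp1 (1.28 ± 0.16), Btg2 (1.18 ± 0.14) and Pfn1, which encodes the actin-binding protein profilin 1 (1.73 ± 0.23). They had less Cdk8, a kinase of the mediator complex (-1.40 ± 0.19), Rpgrip1, a ciliary protein (-1.13 ± 0.14), and Lars2, a mitochondrial leucyl-tRNA synthetase (-1.07 ± 0.14). Adjusted p lay between 0.012 and 0.016 for these 6 genes. Pfn1, Btg2 and Lars2 also passed the test in other classes, CD45-negative cells among them. Naive or memory genes were lower again (median -0.24, adjusted p = 0.0051), with 0 over all genes and 4 adjusted over the list alone, and oxidative phosphorylation genes were lower (median -0.22, adjusted p = 0.00048), with 0 and 9. Type I interferon genes (median 0.20, adjusted p = 0.0022) had 0 and 3 higher, interferon-gamma response genes (median 0.25, adjusted p = 0.016) 0 and 1, and exhaustion genes passed narrowly (median 0.26, adjusted p = 0.0498), with 0 and 0. These 5 lists had adjusted p = 0.959 with an estimated correlation. Of all genes tested, 27 were called, 16 higher and 11 lower. DESeq2 called 19, 6 higher and 13 lower, and thinning to equal totals gave 315.

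Conventional CD4 T cells of the anti-PD-1 library expressed more Penk, which encodes the opioid precursor proenkephalin, at 128 CPM against 38.6 and 16.5 CPM in PBS (log2 fold change 2.22 ± 0.22, adjusted p = 6.8e-20; 2.96 without PBS 1). Tnfsf11, which encodes the cytokine RANKL, fell from 209 and 173 to 81.2 CPM (-1.23 ± 0.21, adjusted p = 3.2e-05). Both genes lead a cluster of this class that held 56, 33, 49 and 71 cells, so they also mark a part of it. Pglyrp1, a peptidoglycan-binding protein, rose by 1.02 ± 0.24 and Timp2, a metalloproteinase inhibitor, rose from 31.6 and 22.5 to 54.0 CPM. Mga, a MAX-binding transcription factor, fell by 1.10 ± 0.25. Handling stress genes were lower (20 genes, median -0.37, adjusted p = 8.9e-05), with 3 over all genes and 7 adjusted over the list alone. Among them were the heat shock genes Hspa1b (-2.10 ± 0.43) and Hspa1a (-1.75 ± 0.40), which differed within the PBS pair. Without PBS 1 the values were -1.45 and -0.78. Oxidative phosphorylation genes were higher (median 0.36, adjusted p = 7.2e-06), with 0 and 11. Regulatory T cell function genes were higher (20 genes, median 0.29, adjusted p = 0.021), with 2 higher and 2 lower over all genes and 6 higher and 2 lower adjusted over the list alone. Members of this list went both ways: Tnfrsf4 was at 0.75 ± 0.19 and Foxp3 at 2.46 ± 0.61 (3.51 and 2.12 CPM against 15.7 CPM). Il2ra was at -1.04 ± 0.25 and Ccr8 at -1.54 ± 0.31 (-0.82 without PBS 1). All 4 are markers used to name regulatory T cells. The 3 lists had adjusted p = 0.975 with an estimated correlation. By edgeR, 43 of 10743 genes were called, 18 higher and 25 lower, while DESeq2 called 0 (103 at an unadjusted p under 0.05) and edgeR without the count filter called 0 (934 at an unadjusted p under 0.05). Keeping doublets ended the calls of Il2ra and Foxp3, and equal totals those of Timp2 and Foxp3.

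In conventional CD4 T cells of the combination library, genes of cytotoxic lymphocytes were higher than in PBS. Gzmb rose from 34.6 and 32.2 to 84.3 CPM (1.33 ± 0.22, adjusted p = 3.1e-06). Klrd1, the NK receptor subunit CD94, rose from 48.6 and 47.9 to 112 CPM (1.21 ± 0.20, adjusted p = 4.6e-06), and Gzma, itself an NK marker here, by 1.24 ± 0.24 (2.01 without PBS 1). Ifitm1, an interferon-induced membrane protein that shares 26.6% of its last stretches with other genes, rose by 1.52 ± 0.23, and Bola2, an iron-sulphur protein, fell by 0.80 ± 0.20, a call that ended at equal totals. A cluster of this class led by St8sia6 and Lef1, a transcription factor of naive T cells, held 79 of 419, 50 of 391, 58 of 486 and 37 of 585 cells. The cytotoxic list (22 genes, median 0.43, adjusted p = 2.6e-06) had 3 members higher over all genes and 9 adjusted over the list alone, with adjusted p = 0.795 with an estimated correlation. Regulatory T cell function genes (median 0.26, adjusted p = 0.014) had 0 over all genes and 2 higher and 2 lower adjusted over the list alone, with adjusted p = 0.862 with an estimated correlation. The 25 genes called, 14 higher and 11 lower, became 0 with DESeq2 (49 at an unadjusted p under 0.05) and 0 without the count filter (720 at an unadjusted p under 0.05, edgeR).

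Between the treated libraries, conventional CD4 T cells of the combination library had more Klrd1 (1.63 ± 0.26), Klrk1, the activating receptor NKG2D and an NK marker here (1.60 ± 0.31), Cebpb, a transcription factor of myeloid cells (2.04 ± 0.30), and Pfn1 (1.63 ± 0.25). They had less Penk (-1.63 ± 0.25), Xcl1, a chemokine for dendritic cells and an NK marker here (-2.13 ± 0.34), and Il31ra, an interleukin-31 receptor subunit (-1.67 ± 0.32). Xcl1 was at 50.4 and 14.4 CPM in the PBS pair, against 51.6 and 11.8 CPM in the treated libraries. Cytotoxic genes were higher (median 0.47, adjusted p = 0.0023), with 3 over all genes and, adjusted over the list alone, 5 higher and 1 lower. Handling stress genes were higher (median 0.20, adjusted p = 0.036), with 4 and 5, among them Hspa1a (2.00 ± 0.43) and Hspa1b (2.09 ± 0.46), and oxidative phosphorylation genes were lower (median -0.29, adjusted p = 0.0022), with 1 and 4. Adjusted p with an estimated correlation was 0.959 for all 3. Of 49 genes called, 28 were higher and 21 lower. DESeq2 called 13, 1 higher and 12 lower, and edgeR without the count filter 0 (879 at an unadjusted p under 0.05). The call of Xcl1 ended with doublets kept.

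Regulatory T cells of the anti-PD-1 library expressed more Ccl3, a chemokine, at 136 CPM against 46.0 and 34.8 CPM in PBS (log2 fold change 1.76 ± 0.18, adjusted p = 0.0011). They had less of the linker histones Hist1h1b (-1.20 ± 0.15, adjusted p = 0.0069), Hist1h1c (-1.07 ± 0.16) and Hist1h1d (-1.37 ± 0.22) and of Rrm2, a subunit of ribonucleotide reductase (-1.68 ± 0.26). These falls were not particular to regulatory T cells, since each of these genes also passed as lower in the other gates. Hist1h1c was lower in 6 of 6 classes, Hist1h1d in 4 of 5, Hist1h1b in 3 of 5 and Rrm2 in 3 of 4. Cell cycle genes fell together (41 genes, median -0.66, adjusted p = 3.3e-15), with 1 over all genes and 21 adjusted over the list alone. A regulatory T cell cluster with Mki67 among its leading genes held 42 of 460, 56 of 448, 42 of 713 and 37 of 617 cells. Cytotoxic genes were higher (22 genes, median 0.39, adjusted p = 2.5e-05), with 1 and 8, as were regulatory T cell function genes (21 genes, median 0.26, adjusted p = 0.012), with 0 and 3. Type I interferon genes (median 0.30, adjusted p = 0.0015) had 0 and 0 past the threshold, oxidative phosphorylation genes (median 0.23, adjusted p = 0.0035) 0 and 0, and macrophage markers (9 genes, median 0.62, adjusted p = 0.0027) 0 and 1. All 6 lists had adjusted p = 0.975 with an estimated correlation. Lars2 (0.89 ± 0.14) and Ifitm3 (0.96 ± 0.16; 28.3% of its last stretches are shared) were the other named rises. By edgeR, 12 of 11627 genes were called, 6 higher and 6 lower. The strict cell filter gave 2, ending the calls of Lars2, Ifitm3, Hist1h1c, Hist1h1d and Rrm2, and thinning to equal totals gave 225.

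In regulatory T cells of the combination library, Klrd1 rose from 14.9 and 11.7 to 67.6 CPM (2.36 ± 0.22, adjusted p = 0.0003) and Ccl3 to 140 CPM (1.81 ± 0.17, adjusted p = 0.0003). Ly6c2, a surface protein that shares 47.7% of its last stretches, rose by 1.88 ± 0.20. The core histones Hist1h2ae (-1.67 ± 0.21), Hist1h2bj (-1.46 ± 0.23) and Hist1h2ab (-1.77 ± 0.29) fell, and each shares over 58% of its last stretches with other histone genes. Cell cycle genes were lower (median -0.59, adjusted p = 9.7e-13), with 0 over all genes and 20 adjusted over the list alone, beside the smaller count of Mki67-led cells given above. Cytotoxic genes were higher (median 0.65, adjusted p = 5.0e-10), with 2 and 11. Regulatory T cell function genes had 0 and 1 (median 0.17, adjusted p = 0.021), NF-kB target genes 1 and 1 (26 genes, median 0.12, adjusted p = 0.011) and macrophage markers 0 and 0 (median 0.37, adjusted p = 0.0044). The 5 lists had adjusted p = 0.795 with an estimated correlation. By edgeR, 17 genes were called, 11 higher and 6 lower. The fit without the anti-PD-1 library called 7, DESeq2 2 and equal totals 122. The strict filter and the fit without that library each ended the calls of Hist1h2bj and Hist1h2ab.

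Klrd1 was also higher in regulatory T cells of the combination library than of the anti-PD-1 library (2.25 ± 0.28, adjusted p = 0.014), as were Btg2 (1.36 ± 0.19) and Pfn1 (1.62 ± 0.24), and Cdk8 was lower (-1.36 ± 0.20). Oxidative phosphorylation genes were lower (median -0.32, adjusted p = 0.00038), with 0 over all genes and 6 adjusted over the list alone. Naive or memory genes were higher (14 genes, median 0.35, adjusted p = 0.016), with 0 and 1. Both had adjusted p = 0.959 with an estimated correlation. By edgeR, 8 genes were called, 4 higher and 4 lower. The strict cell filter called 0 (1013 at an unadjusted p under 0.05, edgeR) and DESeq2 2, and keeping doublets ended the call of Klrd1.

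In monocytes and macrophages of the anti-PD-1 library, interferon response genes were higher than in PBS. Upp1, the uridine phosphorylase, rose from 29.0 and 34.6 to 103 CPM (log2 fold change 1.69 ± 0.11, adjusted p = 4.6e-22), and Ccl5, a chemokine for T cells, from 178 and 151 to 420 CPM (1.36 ± 0.11). Ly6a, the interferon-induced surface protein Sca-1 (13.6% shared), rose by 1.39 ± 0.13 and Slpi, a protease inhibitor and neutrophil marker, by 1.34 ± 0.11. Interferon-gamma response genes rose together (24 genes, median 0.51, adjusted p = 3.6e-07), 19 over all genes and 19 adjusted over the list alone. Among them were Gbp2, a guanylate-binding protein (0.86 ± 0.13), Serpina3g, a protease inhibitor (0.88 ± 0.11, 15.1% shared), Cd274, and Cxcl9, a chemokine for T cells (0.81 ± 0.16). MHC class I genes (17 genes, median 0.37, adjusted p = 0.0016) had 10 higher and 1 lower over all genes, and 11 and 1 adjusted over the list alone. MHC class II genes (10 genes, median 0.45, adjusted p = 0.0041) had 5 and 6 higher, and type I interferon genes (28 genes, median 0.31, adjusted p = 0.0013) 11 higher, and adjusted over the list alone 14 higher and 1 lower. Adjusted p was 0.975 with an estimated correlation for each list of this paragraph. The class held 431, 404, 764 and 657 cells of monocyte clusters and 363, 281, 286 and 318 of macrophage clusters, so by these names the treated libraries held a larger part of monocytes. The monocyte cluster with the most cells (1405) had the macrophage marker C1qa at 1050 CPM and scored 2.04 for monocytes against 1.80 for macrophages. At the higher resolution a cluster of 918 cells with shared leading genes was named macrophage, so this split and values of the monocyte clusters alone depend on that cluster's name.

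Cell cycle genes were lower in monocytes and macrophages under anti-PD-1 (41 genes, median -0.68, adjusted p = 1.4e-15), 31 over all genes and 33 adjusted over the list alone. Among them were Mki67, a marker of dividing cells that shares 21.9% of its last stretches, at -1.03 ± 0.11 and the topoisomerase Top2a at -0.92 ± 0.11. A macrophage cluster with Mki67 at 685 CPM held 83 of 794, 76 of 685, 56 of 1050 and 71 of 975 cells of the class. Within the monocyte clusters alone the direction turned: Mki67 was at 0.13, Top2a at 0.28, and the list had the opposite sign with an adjusted p of 0.385. Lpl, lipoprotein lipase, fell by 1.52 ± 0.14, Mir99ahg, a noncoding host gene, by 1.43 ± 0.12 and Hist1h1b by 1.41 ± 0.12. Oxidative phosphorylation genes (38 genes, median 0.37, adjusted p = 3.6e-07) had 26 and 28 higher. Hypoxia and glycolysis genes (27 genes, median 0.38, adjusted p = 2.7e-06) had 16, and adjusted over the list alone 17 higher and 1 lower. Neutrophil markers (10 genes, median 1.07, adjusted p = 7.1e-05) had 6 and 7 higher and neutrophil maturation genes (16 genes, median 0.59, adjusted p = 0.0049) 5 and 5. Inflammatory myeloid genes (17 genes, median 0.46) passed narrowly (adjusted p = 0.0496), with 4 higher and 1 lower in both counts. With an estimated correlation, each of these lists had adjusted p = 0.975. By edgeR, 1921 of 14491 genes were called, 1060 higher and 861 lower, 214 of them at least 2-fold. DESeq2 called 313, of which 301 were among the 1921, 224 higher and 89 lower, and the monocyte clusters alone gave 84, 61 higher and 23 lower. In these clusters the calls of Serpina3g, Gbp2, Mir99ahg, Lpl and Hist1h1b ended. A fit by edgeR without the count filter gave 0 (3432 at an unadjusted p under 0.05).

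In monocytes and macrophages of the combination library, Gbp2b, another guanylate-binding protein, rose from 11.7 and 15.2 to 59.4 CPM (2.14 ± 0.14, adjusted p = 2.5e-22). Upp1 rose by 1.63 ± 0.11, Ccl5 by 1.62 ± 0.11 and Socs1, a feedback inhibitor of interferon signalling, by 1.48 ± 0.14 (adjusted p = 1.7e-15). Pdcd1lg2, which encodes the ligand PD-L2, rose by 0.88 ± 0.20 and Ptgs2, the cyclooxygenase COX-2, by 0.85 ± 0.11. Interferon-gamma response genes (median 0.58, adjusted p = 1.1e-11) had 18 over all genes and 23 adjusted over the list alone. MHC class I genes had 12 and 15 (median 0.44, adjusted p = 1.2e-07), type I interferon genes 10 and 14 (median 0.29, adjusted p = 3.8e-05) and MHC class II genes 5 and 7 (median 0.45, adjusted p = 0.0081). T cell markers rose beside them (11 genes, median 1.52, adjusted p = 3.1e-09), with 10 and 10. Cd3g rose by 1.84 ± 0.17, Cd8b1 by 1.87 ± 0.20 and Trbc2 by 1.52 ± 0.14. In the same cells Pdcd1 was at 1.39 ± 0.28 and Nkg7, a granule protein and a CD8 marker here, at 1.71 ± 0.20. Cells with at least 2 UMIs of T cell receptor or CD3 genes were 6.42%, 6.86%, 4.57% and 9.95% of the class. Adjusted p with an estimated correlation was 0.795 for interferon-gamma, MHC class I and T cell markers, and 0.847 for type I interferon and MHC class II. The call of Pdcd1lg2 ended in the macrophage clusters alone, and those of Trbc2 and Cd8b1, which share 27.5% and 26.0% of their last stretches with other genes, in the monocyte clusters alone.

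Cell cycle genes were lower in this library too (median -0.40, adjusted p = 1.6e-08), 18 over all genes and 25 adjusted over the list alone, beside the smaller share of cells in the Mki67-high cluster (71 of 975) and with the opposite sign in the monocyte clusters alone (adjusted p = 0.208). Hist1h2ab fell by 1.91 ± 0.14, Hist1h2ae by 1.46 ± 0.11, a call that ended in the monocyte clusters, and Lpl by 1.48 ± 0.13, likewise. Neutrophil markers were higher (median 1.65, adjusted p = 4.2e-08), 8 and 8. Among them was Retnlg, a neutrophil secreted protein, at 3.53 ± 0.42 but only 7.17 CPM. Also higher were neutrophil maturation genes (median 0.58, adjusted p = 2.4e-06), 7 and 8, and tumour-infiltrating neutrophil genes (19 genes, median 0.25, adjusted p = 0.028), 7 higher and 1 lower, and adjusted over the list alone 8 and 3. Hypoxia genes (median 0.31, adjusted p = 3.0e-07) had 11 and 17. Inflammatory myeloid genes (median 0.40, adjusted p = 0.00081) had 6 and 8, and NF-kB target genes (27 genes, median 0.18, adjusted p = 0.019) 6 higher and 1 lower, and adjusted over the list alone 10 and 2. With an estimated correlation, adjusted p was 0.847 for inflammatory myeloid, 0.862 for NF-kB and 0.795 for the other 5 lists. By edgeR, 1161 genes were called, 671 higher and 490 lower, 227 at least 2-fold, DESeq2 137 (97 and 40), the monocyte clusters 119 (102 and 17), the strict cell filter 641 (407 and 234) and edgeR without the count filter 0 (2699 at an unadjusted p under 0.05).

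Compared with the anti-PD-1 library, monocytes and macrophages of the combination library had more Ch25h, the enzyme that makes 25-hydroxycholesterol, at 52.9 against 15.3 CPM and 19.98 and 25.2 CPM in PBS (1.79 ± 0.18, adjusted p = 5.8e-12), more Pfn1 (1.62 ± 0.17) and more Cebpb (1.78 ± 0.28). T cell markers were higher (median 1.54, adjusted p = 1.6e-07), 9 and 10, with Cd3g at 2.57 ± 0.24 and Trac at 1.72 ± 0.22, and Pdcd1 was at 1.86 ± 0.38. Cell cycle genes were higher (median 0.25, adjusted p = 0.00015), 12 and 16, with Cdk1, the mitotic kinase, at 0.99 ± 0.20, and the opposite sign in the monocyte clusters alone (adjusted p = 0.967). Oxidative phosphorylation genes were lower (median -0.38, adjusted p = 8.8e-07), with 1 higher and 20 lower over all genes and 1 and 25 adjusted over the list alone, and tumour-infiltrating neutrophil genes higher (median 0.39, adjusted p = 0.042), 7 and 8. These 4 lists had adjusted p = 0.959 with an estimated correlation. Cdk8 (-1.10 ± 0.14), Lars2 (-0.96 ± 0.13) and Adap2os, a transcript antisense to Adap2 (-0.99 ± 0.16), were lower. Of 1138 genes called, 565 were higher and 573 lower. DESeq2 called 114, 33 higher and 81 lower, and the monocyte clusters 74, 44 higher and 30 lower. In those, Ch25h, Cebpb, Cd3g, Trac, Cdk1 and Adap2os no longer passed. The higher resolution also ended the call of Cebpb, and edgeR without the count filter called 0 (2910 at an unadjusted p under 0.05).

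In neutrophils interferon response lists were higher in both treated libraries, with few genes past the threshold on their own. The mitochondrial share of UMIs in neutrophils was higher in the same libraries (0.840% and 0.934% in PBS, 1.45% under anti-PD-1 and 1.31% in the combination library). Under anti-PD-1, interferon-gamma response genes (20 genes, median 1.05, adjusted p = 3.6e-07) had 0 over all genes and 8 adjusted over the list alone, and type I interferon genes (26 genes, median 0.71, adjusted p = 3.6e-07) 0 and 3. MHC class I genes (median 0.52, adjusted p = 0.022) had 0 and 0, neutrophil maturation genes (18 genes, median 0.59, adjusted p = 0.021) 0 and 1 and oxidative phosphorylation genes (37 genes, median 0.27, adjusted p = 0.039) 0 and 0. MHC class II genes, of which only 6 were tested, were lower (median -1.49, adjusted p = 0.0011), with 0 and 3. The 6 lists had adjusted p = 0.975 with an estimated correlation. Ifitm1 was the 1 gene called by edgeR (586 and 549 to 1744 CPM, 1.62 ± 0.36, adjusted p = 0.043; 303 of 5662 genes at an unadjusted p under 0.05). RLE size factors, the strict filter, doublets kept and DESeq2 (0 called, 38 at an unadjusted p under 0.05) ended that call. A neutrophil cluster led by Cxcl2 held 36, 114, 31 and 32 cells, so most of it came from PBS 2.

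The combination library gave higher interferon-gamma (median 0.63, adjusted p = 3.1e-05) and type I interferon genes (median 0.56, adjusted p = 1.2e-05) in neutrophils, 0 and 4, and 0 and 0. Also higher were MHC class I (median 0.53, adjusted p = 0.00022), 0 and 0, and neutrophil maturation genes (median 0.58, adjusted p = 0.00024), 0 and 0. MHC class II genes were higher here (median 1.09, adjusted p = 3.7e-05), 0 and 4, and T cell markers moved with them (9 genes, median 0.59, adjusted p = 0.0004), 0 and 0. Hypoxia genes (25 genes, median -0.58, adjusted p = 0.00051), 0 and 0, and tumour-infiltrating neutrophil genes (18 genes, median -0.39, adjusted p = 0.023), 1 and 1, were lower. With an estimated correlation, adjusted p was 0.847 for type I interferon and maturation, 0.866 for hypoxia and tumour-infiltrating genes, and 0.795 for the other 4 lists. By edgeR, 2 genes were called. Cd36, a fatty acid receptor of macrophages (2.51 ± 0.52, and 1.85 to 3.33 without 1 PBS library), rose, and Spp1 fell from 1310 and 3241 to 551 CPM (-2.05 ± 0.41; -1.25 without PBS 2). DESeq2 called 0 (19 at an unadjusted p under 0.05), and both calls ended with doublets kept.

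MHC class II genes set the treated libraries apart in neutrophils (median 2.56, adjusted p = 1.6e-08, and 0.959 with an estimated correlation), 3 over all genes and 5 adjusted over the list alone. H2-Aa was at 240 against 32.1 CPM (119 and 75.2 CPM in PBS; 2.89 ± 0.62, adjusted p = 0.0077), and Cd74, the invariant chain, differed by 2.41 ± 0.52 and H2-Eb1 by 2.70 ± 0.64. Gpnmb, a macrophage glycoprotein (4.48 ± 0.99), and Plcb1, a phospholipase C (3.72 ± 0.83), were higher too, and Cd36 was at 135 CPM against 0 UMIs in the anti-PD-1 library, which allows up to 11.1 CPM. T cell markers were higher (median 0.77, adjusted p = 0.045), 0 and 0. Hypoxia genes were lower (median -0.48, adjusted p = 0.0037), 0 and 1. Both lists had adjusted p = 0.959 with an estimated correlation. By edgeR, 8 genes were called, all higher. Keeping doublets gave 0 (215 at an unadjusted p under 0.05) and DESeq2 0 (20 at an unadjusted p under 0.05). The class held 136, 190, 140 and 179 cells.

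CD45-negative cells, which hold tumour and stromal cells, had more interferon-gamma response transcripts and less collagen in the anti-PD-1 library. Igtp, an interferon-induced GTPase, rose by 0.74 ± 0.13 (adjusted p = 0.00018), Ly6a by 1.06 ± 0.12, Lgals3, the lectin galectin-3, from 86.6 and 102 to 210 CPM (1.16 ± 0.13, adjusted p = 2.7e-08) and AA467197, a small interferon-related gene that shares 10.4% of its last stretches, by 0.99 ± 0.12. The coagulation initiator F3 fell by 1.21 ± 0.14, the matrix proteoglycan Ogn by 1.14 ± 0.14, and the collagens Col1a1 by 1.17 ± 0.20, Col5a1 by 0.97 ± 0.14 and Col3a1 by 0.80 ± 0.18, with the fibroblast receptor Pdgfra at -0.62 ± 0.14. Interferon-gamma response genes (25 genes, median 0.48, adjusted p = 0.00016) had 9 over all genes and, adjusted over the list alone, 11 higher and 1 lower. Stroma markers (9 genes, median -0.62, adjusted p = 0.0016) had 4 and 4 lower. Hypoxia genes (26 genes, median 0.33, adjusted p = 0.0012) had 4, and adjusted over the list alone 13 higher and 1 lower, and oxidative phosphorylation genes (median 0.29, adjusted p = 2.4e-05) 3 and 10. T cell markers (11 genes, median 0.75, adjusted p = 0.00017), 1 and 1, and neutrophil markers (8 genes, median 1.17, adjusted p = 0.0046), 1 and 1, were higher beside them, at low levels (Nkg7 at 1.73, 1.26, 3.73 and 3.35 CPM). All 6 lists had adjusted p = 0.975 with an estimated correlation. A collagen-led cluster held 92 of 352, 44 of 159, 61 of 306 and 92 of 508 cells of the class. By edgeR, 638 of 15140 genes were called, 348 higher and 290 lower, 89 at least 2-fold. DESeq2 called 109 and the strict cell filter 970.

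In the combination library, CD45-negative cells had more Cryab, a small heat shock protein that is among the leading genes of 1 cluster of the class (18.8 and 20.6 to 72.5 CPM, 1.89 ± 0.13, adjusted p = 2.0e-17), AA467197 (1.22 ± 0.12) and Nos2, the inducible nitric oxide synthase (1.18 ± 0.13). Also higher were the interferon-induced GTPases Iigp1 (1.01 ± 0.14) and Igtp (0.95 ± 0.12). Ero1l, an oxidase of the endoplasmic reticulum, rose by 0.85 ± 0.13. They had less Ogn (-1.19 ± 0.13), Gas7 (-0.93 ± 0.13), Trp53i11 (-0.83 ± 0.13) and Col1a1 (-0.88 ± 0.18). Interferon-gamma response genes (median 0.62, adjusted p = 1.1e-11) had 14 over all genes and, adjusted over the list alone, 19 higher and 1 lower. Genes for neutrophil and monocyte attractants (12 genes, median 0.56, adjusted p = 0.00051) had 2 and 7. NF-kB target genes (25 genes, median 0.24, adjusted p = 0.008) had 2 and 5, and hypoxia genes (median 0.27, adjusted p = 1.2e-06) 7 and 9. MHC class I genes (median 0.23, adjusted p = 0.0021) had 3 and 3, and MHC class II genes (9 genes, median 0.79, adjusted p = 0.0021) 4 and 4. H2-Aa rose by 1.49 ± 0.28, but at 6.46 CPM it stood far below the 2006 CPM in monocytes and macrophages of the same library, and its call ended with doublets kept. T cell markers (median 1.01, adjusted p = 1.5e-08), 0 and 2, and neutrophil markers (median 0.72, adjusted p = 0.0045), 0 and 0, were higher and stroma markers (median -0.64, adjusted p = 0.002) lower, 4 and 4. With an estimated correlation, adjusted p was 0.859 for MHC class I, 0.847 for MHC class II and 0.795 for the other 7 lists. By edgeR, 364 genes were called, 203 higher and 161 lower, 85 at least 2-fold, and DESeq2 43, of which 42 were among the 364.

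Between the treated libraries, CD45-negative cells of the combination library had more Pfn1 (1.76 ± 0.19), Zfp36, an RNA-destabilising protein (1.48 ± 0.19), Magohb, a splicing factor (1.40 ± 0.16, 20% of its last stretches shared), the MHC class Ib gene H2-M3 (1.39 ± 0.19) and Socs1 (0.85 ± 0.19). They had less Polr2l, an RNA polymerase subunit (-1.07 ± 0.15, 19.4% shared). Interferon-gamma response genes were higher (median 0.26, adjusted p = 0.0053), 2 over all genes and 5 adjusted over the list alone. So were handling stress genes (19 genes, median 0.11, adjusted p = 0.045), 3 and 5. Oxidative phosphorylation genes were lower (median -0.32, adjusted p = 1.4e-05), 7 and 13. The 3 lists had adjusted p = 0.959 with an estimated correlation. By edgeR, 442 genes were called, 293 higher and 149 lower. DESeq2 called 61, 39 higher and 22 lower, and the strict filter 767.

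**Figure D4:**
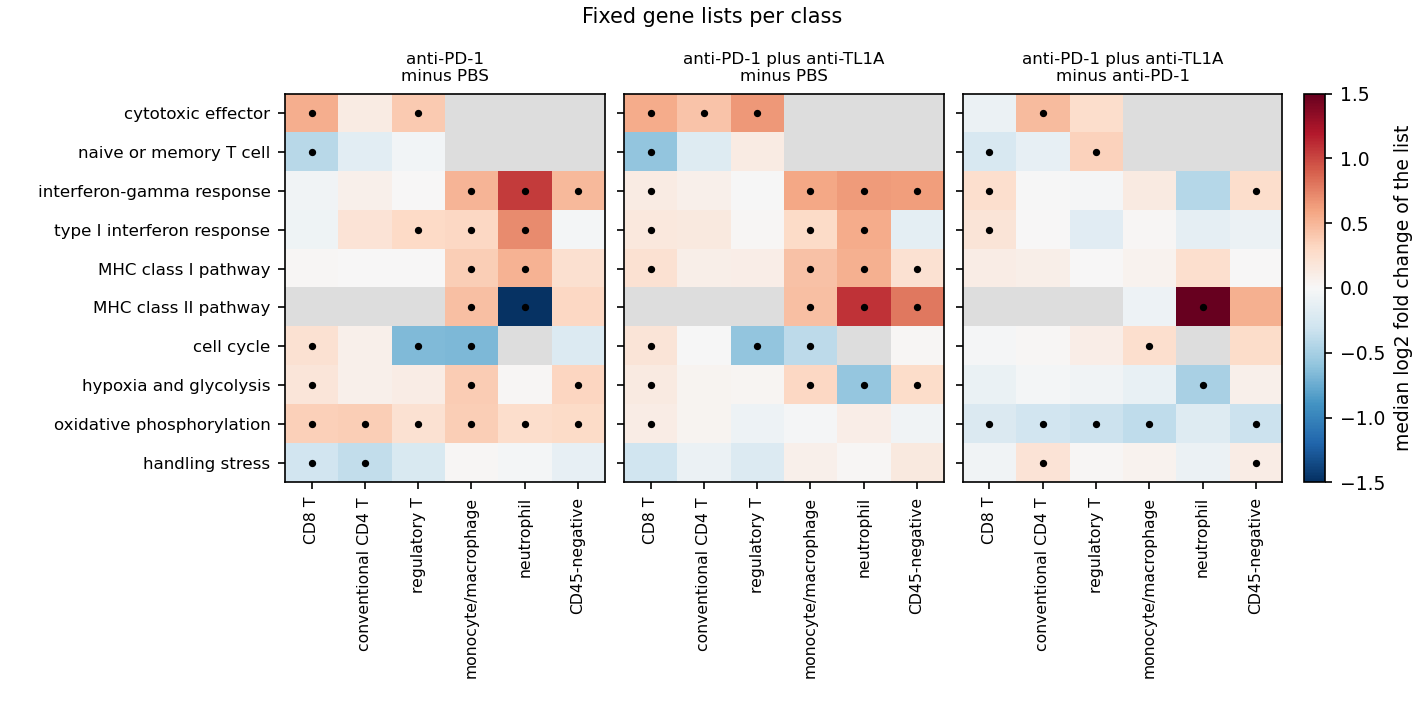
Median log2 fold change of 10 fixed gene lists in 6 classes for the 3 comparisons, with a dot where camera's adjusted p with the preset correlation was under 0.05 and grey where a list was not tested. Colours end at 1.5 in either direction. Oxidative phosphorylation is higher in all 6 classes of the anti-PD-1 library and lower in 5 of 6 classes of the combination library against it, and no dot remains with an estimated correlation.

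Some genes differed in the same direction across gates. In at least 1 class of each gate, 27 genes were higher and 8 lower under anti-PD-1 than in PBS, 15 and 6 in the combination library, and 17 and 9 between the treated libraries. Pfn1 was higher in the combination than in the anti-PD-1 library in 6 of 6 classes (log2 fold changes 1.62 to 2.01) and passed the test in each. Btg2 (0.67 to 1.36) and Zfp36 (1.05 to 1.48) were higher in 6 of 6 and passed in 5, and Lars2 (-1.43 to -0.79) was lower in 6 of 6 and passed in 4. Oxidative phosphorylation genes were higher in all 6 classes under anti-PD-1. As median log2 ratios of CPM after adding 2 CPM, the list's rise in neutrophils (0.36) lay under the difference between the PBS libraries (0.38), and that in regulatory T cells was 0.25 against 0.22 in the PBS pair. In the other 4 classes it was 0.30 to 0.38 against 0.074 to 0.27. Beside it, the share of UMIs from the nuclear RNA Malat1 was lower under anti-PD-1 than in both PBS libraries in each of the 6 classes (1.09%, 1.17% and 0.922% in CD8 T cells). The share of ribosomal protein genes was above both in 4 of 6 (23.5%, 21.9% and 26.6% in CD45-negative cells). Across the lists, camera with the preset correlation called 39 of 104 tests under anti-PD-1, 32 higher and 7 lower, 47 in the combination library, 41 higher and 6 lower, and 20 between the treated libraries, 13 higher and 7 lower. No list passed with an estimated correlation, a test that has 1 degree of freedom here. Lists of T cell cytokines, pro-apoptotic, anti-apoptotic, epithelial-mesenchymal transition and tumour-associated macrophage genes and markers of B cells, erythroid cells and tumour cells passed in no class or comparison.

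The changes in the treated libraries were compared with each other, which shares the PBS pair. In CD8 T cells, 19 genes were higher and 4 lower in both treated libraries, against 0.365 and 0.0725 for independent lists. Monocytes and macrophages shared 243 higher and 214 lower genes against 49.1 and 29.1, CD45-negative cells 42 and 55 against 4.67 and 3.08, regulatory T cells 1 and 0, and conventional CD4 T cells and neutrophils 0. The 20 simulations of unchanged groups gave 0 shared calls in each class. Across genes, which are not independent replicates, log2 fold changes correlated at 0.466 in CD8 T cells against 0.355 in simulations, at 0.349 against 0.288 in monocytes and macrophages and at 0.412 against 0.322 in CD45-negative cells. Covariances were 0.105 against 0.0459, 0.115 against 0.0407 and 0.132 against 0.0554. In conventional CD4 T cells, regulatory T cells and neutrophils they were 0.0990 against 0.0592, 0.0892 against 0.0496 and 0.196 against 0.126. The share of genes with the same sign was 64.2% against a simulated 61.7% in CD8 T cells, 62.0% against 60.3% in monocytes and macrophages and 64.2% against 59.8% in neutrophils. It lay below the simulations in CD45-negative cells (59.6% against 61.3%), conventional CD4 T cells (60.4% against 60.7%) and regulatory T cells (60.3% against 60.8%). The PBS pair could not be split, so part of the excess may come from the shared controls.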

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

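The pattern tests were written down before they were run, but after the gene and list results had been seen; which PBS bound to use, the weighting by cells and the 20 draws were settled after a first run, and the outcome for transcript length depends on the bound. Low-UMI clusters held 26.7% of the kept cells of the anti-PD-1 library (3081 of 11523; 95% interval 25.9 to 27.6), against 5.66% and 14.1% in the PBS pair and 2.31% in the combination library, a signal in cells that the comparisons leave out. Clusters with markers of 2 lineages held 8.21% of the cells of the combination library (815 of 9932; 7.67 to 8.76), against 4.90% and 6.41% in PBS and 4.75% under anti-PD-1. NK cells, outside the 6 classes compared, made up 47.8% (46.1 to 49.5) of CD3-negative immune cells under anti-PD-1 and 52.9% (51.3 to 54.6) in the combination library, against 40.1% and 39.8% in PBS. The log2 ratio of NK cells over PBS under anti-PD-1 went from 0.26 to 0.089 with low-UMI clusters kept and to 0.20 at the higher resolution. These 3 differences were not tested. No group had the 4 libraries that a test for outlying libraries needs.

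Cytotoxic effector genes were higher in CD8 T cells of both treated libraries. With each CD8 cluster weighted by its mean PBS share, the list's median log2 ratio went from 0.56 to 0.43 under anti-PD-1 and from 0.56 to 0.307 in the combination library, against 0.08 between the PBS libraries, so a different mix of clusters does not account for all of it. In the CD8 cluster with the most cells (1531) it was 0.31 and 0.13, against 0.028 between the PBS libraries. Free RNA from other cells was tested by the summed CPM of granzymes and Prf1, whose rise in B cells or CD45-negative cells was at most 0.0310 of the rise in CD8 T cells. A response of CD8 T cells to either treatment may therefore be part of the pattern, as a hypothesis that 1 library per arm cannot separate from differences between libraries.

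Interferon-gamma response genes were higher in monocytes and macrophages of both treated libraries. With clusters weighted by their mean PBS share, the lower of the 2 medians was 0.367, and without cells that held 2 or more UMIs of T cell receptor or CD3 genes it was 0.489, against 0.15 to 0.18 between the PBS libraries. Within single clusters, the anti-PD-1 median lay under the difference of the PBS pair in a macrophage cluster of 865 cells (0.32 against 0.37) and in one of 97 cells (1.06 against 1.35), where the combination library did too (1.26). Neither the mix of clusters nor captured T cells accounts for all of the pattern in the class. A response to interferon-gamma may be part of the pattern, a hypothesis with the same limit of 1 library per arm.

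Oxidative phosphorylation genes were higher in all 6 classes of the anti-PD-1 library, whose cells were the shallowest, though in neutrophils by less than the PBS libraries differed (0.36 against 0.38). Among cells matched on UMIs per cell over 20 draws, the list's median was 0.385 in neutrophils, its lowest class, where single draws ranged from 0.20 to 0.49, and it kept the bound in 5 or 6 of the 6 classes depending on which PBS difference was used. Fewer UMIs per cell therefore do not account for all of it, although matching in a shallower library selects larger cells. The list's transcripts are short (median 896 bases against 3107 in CD8 T cells), and after subtraction of the median of genes of like length the lowest median was 0.0973. The bound was then met in 3 or 4 of the 6 classes depending on which PBS difference was used, with 4 needed to exclude length as the whole cause, so transcript length and a biological difference cannot be told apart here, and length may account for a part.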

How the results depend on the processing

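Tests added after the data were seen were those named as such under processing, all of NK cells and the axis values without 1 PBS library. No paired analysis was possible because the groups share fewer than 2 replicate numbers. Without 1 PBS library no residual degree of freedom was left, so only values are given. Of 1919 comparisons of single genes with an alternative, 1656 kept their direction and side of the threshold, 169 no longer passed, 92 moved without 1 PBS library and 2 reversed; of 947 of single lists, 785 kept theirs, 159 no longer passed and 3 reversed. Neutrophils had the smallest sums of the 6 classes compared (271386 to 642024 UMIs) and the largest biological coefficient of variation (23.9%), and which of these limits their calls was not tested. Where a cause is not named, the cause was not tested. With an estimated correlation, lists past the threshold went from 39, 47 and 20 to 0, 0 and 0 (camera); that test has 1 degree of freedom, and whether this or the correlation ended the calls was not tested; the other settings gave 35 to 40, 43 to 48 and 17 to 23.

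Counts below are genes past the threshold in the order anti-PD-1 minus PBS, combination minus PBS, combination minus anti-PD-1, where they moved by over 1.5 times. In CD8 T cells (main 81, 153 and 27), no filter gave 563, 737 and 285, the strict cell filter 205, 261 and 78, the higher resolution 476, 597 and 228, low-UMI clusters kept 387, 259 and 100, names before the top 10 rule 286, 247 and 82, and equal totals 716, 704 and 315. RLE gave 149 in the first and 63 in the last, doublets kept 172 and 62, and DESeq2 47 in the first and 49 in the middle one. In conventional CD4 T cells (43, 25 and 49), no filter gave 0, 0 and 0 (934, 720 and 879 at an unadjusted p under 0.05, edgeR) and DESeq2 0, 0 and 13 (103 and 49 at an unadjusted p under 0.05 for the first pair); for the combination against PBS, the higher resolution gave 38 and equal totals 16. In regulatory T cells (12, 17 and 8), no filter gave 159, 107 and 56, the strict filter 2, 7 and 0 (edgeR, 1013 at an unadjusted p under 0.05, DESeq2 2), the higher resolution 24, 37 and 25, low-UMI clusters kept 68, 41 and 15, and equal totals 225, 122 and 80. Doublets kept gave 22 in the first, DESeq2 2 and 2 in the others, and the fit without the anti-PD-1 library 7.

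In monocytes and macrophages (1921, 1161 and 1138), no filter gave 0, 0 and 0 (3432, 2699 and 2910 at an unadjusted p under 0.05, edgeR), DESeq2 313, 137 and 114, and monocyte clusters alone, with fewer cells, 84, 119 and 74. Macrophage clusters alone gave 1232 in the first and 696 in the last, the strict filter 641 and 569 in the others, and doublets kept 1800 in the last. In monocyte clusters alone, Mki67 went from -1.03 to 0.13 and Top2a from -0.92 to 0.28 under anti-PD-1, and the cell cycle list turned its direction with adjusted p of 0.385, 0.208 and 0.967 in the 3 comparisons. In neutrophils (1, 2 and 8), anti-PD-1 minus PBS gave 0 with RLE, no filter and the strict filter (edgeR, 291, 415 and 274 at an unadjusted p under 0.05) and 0 with DESeq2 (38). The combination against PBS gave 1 with doublets kept and 0 with DESeq2 (19), and the treated libraries 3 with no filter, 0 with doublets kept (edgeR, 215) and 0 with DESeq2 (20), each at an unadjusted p under 0.05. In CD45-negative cells (638, 364 and 442), DESeq2 gave 109, 43 and 61, the strict filter 970 in the first and 767 in the last, RLE 550 in the middle one and doublets kept 289 in the last.

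Of log2 ratios of class shares over PBS, that of CD8 T cells went from 0.07 to 0.38 under anti-PD-1 with low-UMI clusters kept and from 0.16 to 0.11 in the combination library at the higher resolution and to 0.10 with mixed clusters kept. Conventional CD4 T cells went from -0.33 to -0.67 with low-UMI clusters kept, and monocytes and macrophages from -0.16 to 0.22 with them and to -0.054 at the higher resolution, all under anti-PD-1. Regulatory T cells went from 0.06 to -0.094 with low-UMI clusters kept and to 0.16 at the higher resolution under anti-PD-1, and from -0.40 to -0.24 at the higher resolution and to -0.034 with mixed clusters kept in the combination library. Neutrophils went from -0.91 to -1.24 with low-UMI clusters kept and ranged from -1.21 to -0.53 without 1 PBS library under anti-PD-1, and from -0.89 to -0.21 in the combination library (main -0.59).

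Of log2 ratios of the share of cells with a UMI, thinning to 1000 UMIs per cell moved Pdcd1 in CD8 T cells from -0.01 to 0.125 under anti-PD-1 and from 0.27 to 0.20 in the combination library, in conventional CD4 T cells from 0.06 to 0.74 and from 0.37 to 0.60, and in regulatory T cells from -0.20 to 0.52 under anti-PD-1. Cd274 moved in monocytes and macrophages from 0.03 to 0.67 and from 0.24 to 0.88, in neutrophils from 0.16 to 0.42 and from 0.13 to 0.33, and in CD45-negative cells from -0.13 to 1.89 and from 0.10 to 1.40. Tnfrsf25 moved in conventional CD4 T cells from -0.37 to 0.97 and from -0.87 to 0.28, on 31, 33, 29 and 23 UMIs. Depth per cell differed between the libraries before thinning, which makes it equal. Without 1 PBS library, Pdcd1 in CD8 T cells ranged from -0.16 to 0.16 under anti-PD-1 and from 0.12 to 0.44 in the combination library, Cd274 in monocytes and macrophages from 0.18 to 0.30 in the combination library, and in neutrophils from 0.0086 to 0.33 under anti-PD-1 and from -0.019 to 0.30 in the combination library.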

Other observations

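NK cells were fitted as a further class only after their share had been seen, so all tests of this part were chosen after the data were examined. In NK cells of the anti-PD-1 library, 3 granzyme genes rose against PBS, with no test of a list: Gzmf rose from 54.4 and 48.1 to 307 CPM (log2 fold change 2.58 ± 0.14, adjusted p = 5.7e-67, edgeR), Gzmd by 1.73 ± 0.14 and Gzmg by 3.16 ± 0.23 (3.96 without PBS 1; doublets kept ended this call). These granzymes share bases with each other, as in CD8 T cells. Cebpb, a transcription factor, fell by 1.16 ± 0.16, the mitochondrial chaperone Hspd1 fell by 0.76 ± 0.15 and Pfn1 fell by 0.91 ± 0.21. Of 3 NK clusters with Gzma, a marker used for naming, as their first leading gene, that with the fewest UMIs per cell (median 2425, close to the minimum of 2000 for a class) held 24, 9, 171 and 57 cells in PBS 1, PBS 2, anti-PD-1 and combination, and the others held 185, 202, 329 and 487, and 159, 103, 310 and 269. Most of the first came from the anti-PD-1 library. edgeR called 103 of 13461 genes, 62 higher and 41 lower, and DESeq2 19.

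In NK cells of the combination library, Gzmd rose by 1.28 ± 0.14 and Gzme by 1.10 ± 0.14 against PBS, while the hexokinase Hk2 fell by 0.87 ± 0.17 and Mcm3, a replication helicase subunit, fell by 0.77 ± 0.16; edgeR called 103 genes, 54 higher and 49 lower, and DESeq2 4. Against the anti-PD-1 library, Cebpb (1.99 ± 0.18), Zfp36 (1.58 ± 0.17) and Pfn1 (1.64 ± 0.24) were higher and Gzmg (-1.69 ± 0.24), the metal-binding protein gene Mt1 (-1.32 ± 0.19) and Cdk8 (-1.31 ± 0.22) lower, with 155 genes called by edgeR, 62 higher and 93 lower, and 22 by DESeq2. That comparison is of 2 libraries, not of the conditions. With clusters named before the top 10 rule the 3 counts were 238, 276 and 189, and with the strict filter 63, 77 and 130. Median UMIs per NK cell were 7062, 7377, 4342 and 5567.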
